A study of Arabidopsis thaliana with 5 samples.

How the data were processed

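Small RNAs of 15 to 35 nt from the rosettes of 4-week-old Arabidopsis thaliana Columbia-0 plants were sequenced in 5 transgenic reporter lines, with 1 library per line. Per the labels' protocols, total RNA was made into libraries and read on 2 lanes of an Illumina sequencer per sample. The lanes are not separated in the values, so no lane comparison was made. The deposited count of each library is the raw number of reads per distinct sequence, in whole numbers and without normalization. Beside each count, the authors gave a yes or no flag for a match to the genome and another for a match to the transgene. Per the submitters' processing notes, CASAVA 1.8.2 and Bowtie were used with the TAIR10 genome. The Bowtie version, the mismatches allowed, the adapter trimming and the transgene sequence behind the flags are not given in the sources used here. Sequences with the flags included ones with no exact match in the genome, so the flags allowed mismatches, and exact matches were recomputed.

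Each sequence was matched exactly, on both strands, to the TAIR10.1 assembly with its RefSeq annotation in Python 3.11.15, with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Levels are reads per 1000000 reads of 15-35 nt (RPM). Depth was 16714109 reads in 390-5d-390c, 23053255 in 390c-5d-390c, 8423269 in 390c-3d-390c, 12398586 in 390c-3d and 15823895 in 390-3d. A floor of 3 counts stood for a count of 0 and was 0.179, 0.130, 0.356, 0.242 and 0.190 RPM in the same order. Sequences with an undetermined base, near 0.14% of the reads, could not match exactly.

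Reporter siRNAs were fixed by rule as the 21-nt sequences that matched CHLI1 exactly, or that had no exact match in the genome, reached 10 RPM in at least 1 library and overlapped a joined contig by at least 15 nt. The rule left 329 sequences with no genome match, and the contigs joined from them also held vector sequence, which is given apart. For the count, overlap was taken with the reporters as rebuilt from the reads (below) in place of the contigs, a choice that rests on the data. Of the 329 sequences, 32 lay on the TAS3a part of a reporter and were counted, 29 of them exact to a reporter. CHLI1 gave 121 sequences. The labels do not spell out 390, 390c, 5d and 3d, so their meaning was read from the reads: each reporter was built as TAS3a with the edits that the reads showed. The share of its 18-nt windows, from position 520 of TAS3a on, that the same reads covered is given, which is no independent check. Sequence further upstream was not reconstructed. Insert siRNAs are 21-nt reads that overlap the artificial insert and match the library's own reporter exactly. They were added as a measure after the data were examined, because the fixed rule counts more sequences where the 390c site is present. Where the reporters of a pair differ in sequence, ratios over the sequences that both hold are given as well.

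Registers were counted in steps of 21 nt from the first base 3′ of the cut at the 5′ site, with antisense reads shifted by 2 nt, over reads between the sites. The cut was placed opposite miR390 nucleotides 10 and 11 at each site, as a reference position. Whether a site was cut there was not tested. Endogenous loci were counted by exact 21-nt matches. A TAS3a read that the reporter also holds cannot be assigned to either, so reads that both reporters of a pair lack are given beside the total. MicroRNAs were counted by exact mature sequence, 350 distinct sequences for 428 annotated mature names, and names with identical sequence were counted together.

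Comparisons were ratios of RPM between 2 libraries, with exact conditional binomial 95% intervals, and shares with exact Clopper-Pearson 95% intervals. With 1 library per line no test was made. Reads were amplified and carried no molecular identifiers, so intervals and floors cover counting error only. A microRNA or gene passed the rule of size with at least 100 reads over the 2 libraries and a fold of 2 or more. Named in the text were every fixed item (miR390, the TAS loci, CHLI1 and reporter siRNAs), up to 5 microRNAs and up to 5 other genes with the highest and the lowest ratio per comparison among those past the rule, and the 5 most abundant siRNAs of the reporter and of TAS3a. Genes of miRNA, TAS, rRNA, tRNA, snRNA or snoRNA were left out of the gene rule, but other genes that overlap a tRNA were not and are marked as such. Lists of 27 microRNA families and of 10 PPR phasiRNA genes were fixed as well. Further items are marked where they were chosen after their values were seen. The lines, comparisons, measures, lists and most alternatives were fixed before the data were examined, apart from the rebuilt reporters and the insert siRNAs described above.

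Alternatives were scaling by mature microRNA reads or by genome-matched 21-nt reads, 20-24 nt reads, distinct sequences, a wider register, an 18-28 nt denominator, single-position reads, microRNA variants, and other minimum counts. Scaling by mature microRNA reads was of weight because these made up 18.6, 16.1, 8.23, 13.4 and 13.6% of reads in the order of depth above. The insert alone, insert siRNAs that both reporters of a pair can make, the exact insert unit, gene counts per microRNA read or by single-position reads, all reporter-only sequences, all reporter matches and TAS3a reads absent from the library's own reporter or from both reporters of a pair were added after the data were examined. The ratio rule was tested on simulated data in which 200 genes changed by a fold of 4. It recovered 100% of them in each comparison, among 1732, 733, 1076 and 1414 genes for the site pair in the 5d lines, the removal of the 3′ site, the site pair in the 3d lines and the insert pair. Of unchanged genes 0.0653, 0, 0 and 0.0824% passed, and 95.5, 94.5, 97.0 and 95.0% of intervals held the true ratio. These simulations held counting error and no difference between plants. The simulated fold of 4 lay above the rule's fold of 2, so the recovery says nothing of changes near that cutoff. The simulated gene numbers also differ from the 1192, 314, 612 and 947 genes compared in the data.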

Results

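The libraries asked which miR390 sites a TAS3 transcript needs to make trans-acting siRNAs (tasiRNAs). TAS3a (AT3G17185) is a noncoding gene on chromosome 3, positions 5861491 to 5862437 of TAIR10.1, plus strand. Its RNA is bound at 2 sites by miR390 loaded in AGO7, is copied by RDR6 and is diced by DCL4 into 21-nt siRNAs that target auxin response factors. Each of 5 lines carried a reporter version of TAS3a, and 1 rosette library was made per line, so no difference between lines has a replicate check. Libraries held 8423269 to 23053255 reads of 15-35 nt. Intervals are 95% and cover counting error only.

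The reporters differed at the 5′ site, the insert and the 3′ site. The 5′ site (609 to 629 of TAS3a, chromosome 3 positions 5862099 to 5862119) lay in an exon of both annotated transcripts, as did the 3′ site (853 to 873, positions 5862343 to 5862363). Lines labelled 390 at the front carried the native 5′ site, GGTGTTATCCTATCTGAGCTT, with 5 differences from a perfect complement of miR390 (C3T, C5T, C11T, T12A and C13T). Positions run from 1 at the 5′ end of the site, and the first base is that of the perfect complement. Lines labelled 390c at the front carried GGCGCTATCCCTACTGAGCTT, with 1 difference (C13A). A final 390c in the label went with the native 3′ site TTGTCTATCCCTCCTGAGCTA, which had 5 differences, and lines without it carried CACGATAGGGAGAGATAGAAA in its place, with 15. The insert held 2 copies of TTAAGTGTCACGGAAATCCCT, which had no exact match in the genome, at 696 to 737 of TAS3a in 5d lines and at 704 to 745 in 3d lines. The 5d insert started a whole number of 21-nt units from the cut at the 3′ site, and the 3d insert from the cut at the 5′ site. Between 97.1 and 100% of the 18-nt windows of each reporter were read, but most windows also lie in endogenous TAS3a. Of windows absent from TAS3a, 58 of 58 were read in 390-5d-390c, 86 of 86 in 390c-5d-390c and 85 of 85 in 390c-3d-390c. In 390c-3d 119 of 122 were read and in 390-3d 92 of 94. The same reads gave the edits, so this is no independent check. Reads specific to another reporter made up 0.0963 to 0.644% of reporter-specific reads.

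All reporters gave 21-nt siRNAs from both strands, those without a 3′ site included. Reads with an exact match to the reporter reached 4636 RPM in 390-5d-390c, 3512 in 390c-5d-390c, 1955 in 390c-3d-390c, 2170.1 in 390c-3d and 2435 in 390-3d. Between the sites they were antisense for 85.2 to 89.3% and peaked at AGAATAGAATCTGTAAAACGA (765 to 785 of TAS3a), at 1055, 665, 312, 273 and 752 RPM in the same order. This siRNA and the next most abundant one, TATTGGATCCGCTGTGCTGAG from upstream of the 5′ site (327, 336, 278, 311 and 84.1 RPM), lie in TAS3a and the reporter alike. Upstream reads were sense for 77.7 to 86.8%. Sequence from the 3′ site on gave 72.1 and 46.4 RPM in the 5d lines and 13.3, 7.90 and 13 RPM in the 3d lines.

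**Figure D1:**
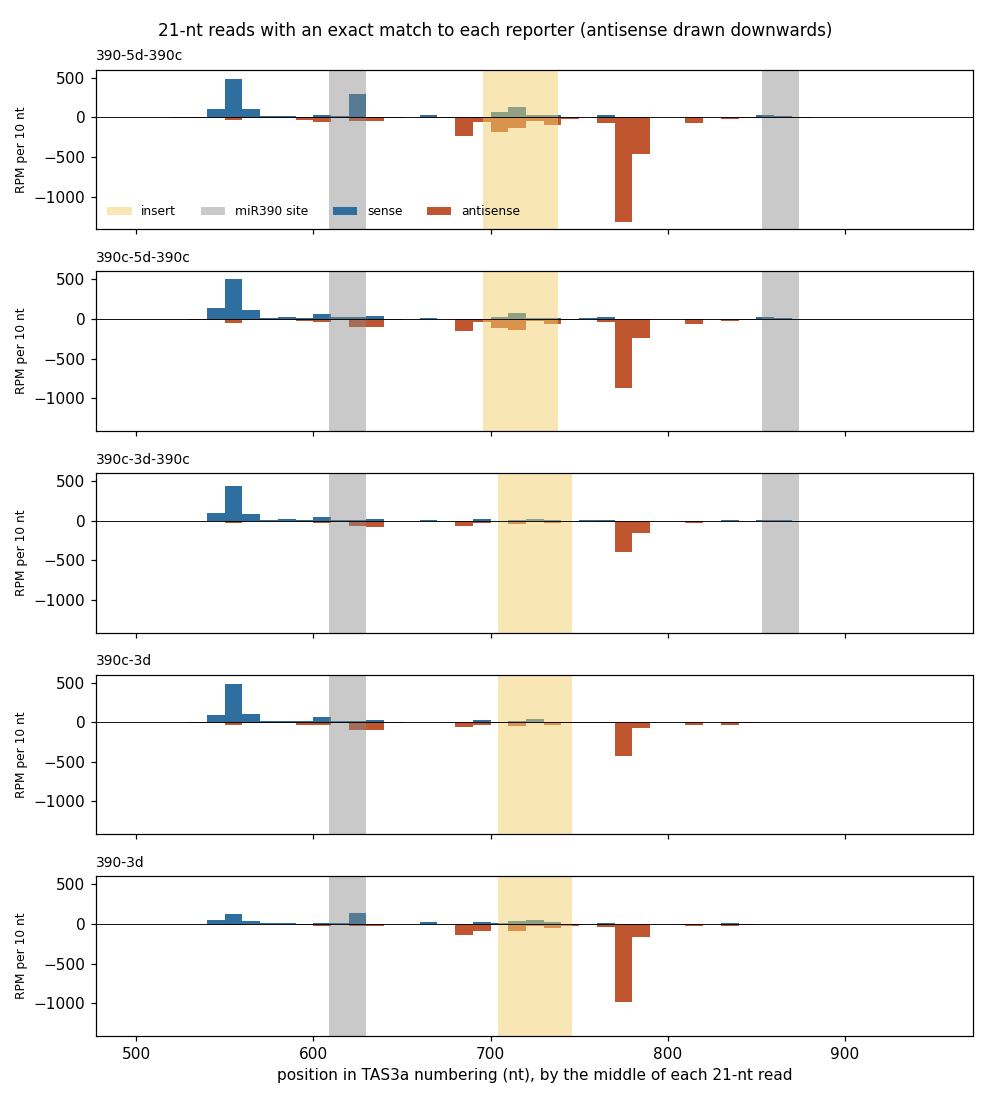
21-nt reads with an exact match to each reporter, in RPM per 10 nt of TAS3a numbering (x axis, nt), sense upwards and antisense downwards, for the 5 libraries. Upstream reads (949 RPM in 390c-3d against 324 in 390-3d) were mostly sense and reads between the sites mostly antisense.

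Insert siRNAs, the reads that overlapped the insert, with flanking TAS3a sequence in part of them, were measured at 862 RPM in 390-5d-390c (848 to 876), 580.3 in 390c-5d-390c (571 to 590.2), 118 in 390c-3d-390c (111 to 125), 183 in 390c-3d (175 to 190.4) and 316 in 390-3d (307 to 325). The most abundant by mean RPM was ACTTAAAGGGATTTCCGTGAC, at 137, 131, 6.41, 9.84 and 17.4 RPM. TCACGGAAATCCCTTTAAGTG reached 109, 54.3, 12.8, 25.4 and 29.1 RPM, and ATTTCCGTGACACTTAAAGGG 37.2, 24, 25.3, 35.6 and 47.5 RPM. TTTCCGTGACACTTAAAAAAG, which spans the insert's edge in the 5d lines, gave 140.0 and 82.5 RPM there and 0 reads in the 3d lines, which allows up to 0.356 RPM. AAATCCGACTAAAAGCTCAGT covers the 390c site and gave 70.1, 57.9 and 70.6 RPM in the 390c lines against 0.299 and 0.253 RPM in the 390 lines. The exact unit was rare, at 1.56 to 6.61 RPM.

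Reads of insert siRNAs gathered in a few registers, the most used of which lay at or within 2 nt of that of the 5′ site. In the 5d lines the most used register was that of the cut position at the 5′ site, with 26.8% of reads in 390-5d-390c (26.1 to 27.5) and 33.2% in 390c-5d-390c (32.5 to 34.1). With the native 5′ site this cut is only a reference position. Of the sense reads that began within that site, 0.276% in 390-5d-390c and 0.243% in 390-3d began there. An even spread gives 4.76%. In the 3d lines the most used register lay 2 nt from that of the 5′ site in 390c-3d-390c (31.6%, 28.7 to 34.5) and in 390c-3d (28.9%, 27.1 to 30.8), and 1 nt from it in 390-3d (33.3%, 32.0 to 34.6). The 5′ site's register itself, to which the 3d insert was set, held 2.42, 3.66 and 1.26% in the same order, below the even share. The register of the cut at the 3′ site, register 13, held 0.444, 0.329, 1.51, 0.177 and 0.360% of reads, although the 5d insert was set to it. Registers 10, 11 and 12, just upstream of it, held 18.2, 7.76 and 6.63% in 390-5d-390c and 15.7, 7.63 and 3.87% in 390c-5d-390c. Register 14, on its other side, held 0.292 and 0.299% there. A place near the 3′ site's register is therefore not excluded for the 5d insert. Counted by distinct sequences, the most used register of insert siRNAs held 6.90, 6.25, 8.51, 8.06 and 7.89%, so the preference rested on a few abundant siRNAs. Reporter siRNAs under the fixed rule had 30.8, 32.6, 23.5, 21.9 and 44.5% of reads in their most used register. The rule kept 32 sequences without a genome match for their abundance, which leaves many registers with 0 reads. These shares therefore do not show phasing against an even spread.

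**Figure D2:**
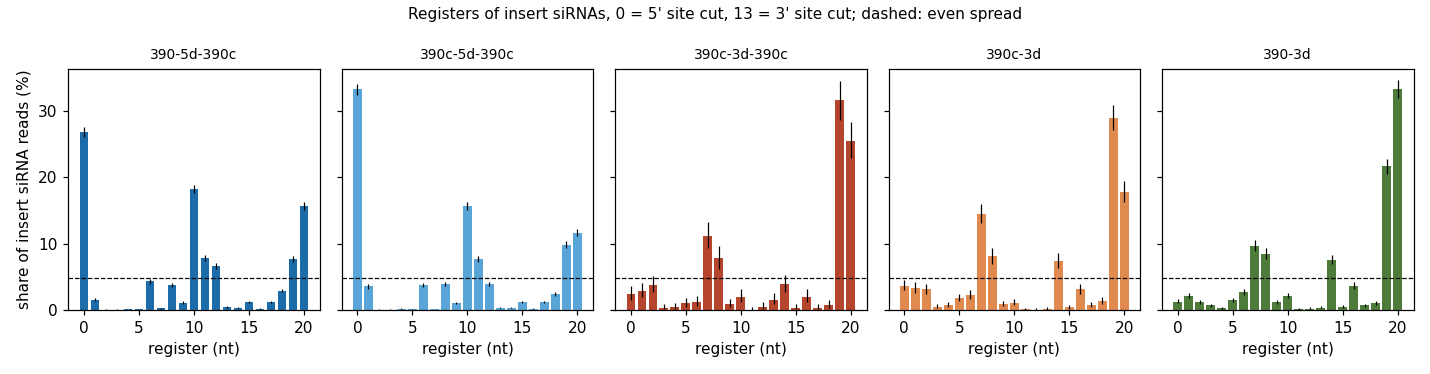
Share of insert siRNA reads (y axis, %) in each of the 21 registers (x axis, nt from the register of the cut at the 5′ site) in the 5 libraries, with exact 95% intervals and a dashed line at the even share of 4.76%. The highest bar is register 0 in both 5d libraries (26.8 and 33.2%) and lies 1 or 2 nt from it in the 3d libraries, while register 13, that of the 3′ site, holds at most 1.51%. Near register 13, register 10 holds 18.2 and 15.7% in the 5d libraries. Register 0 holds 2.42, 3.66 and 1.26% in 390c-3d-390c, 390c-3d and 390-3d.

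TAS3a as a whole used the 5′ site's register for 38.8 to 44.9% of its reads between the sites. The antisense siRNA at 765 to 785 gave 17633 of these 19511 reads in 390-5d-390c and 15329 of 17155 in 390c-5d-390c. In the 3d lines it gave 2630 of 2972 in 390c-3d-390c, 3384 of 4041 in 390c-3d and 11894 of 12643 in 390-3d. TAS3a and the reporters both hold this siRNA, so this share alone does not show phasing of TAS3a from the 5′ cut. The register of its 3′ site held 2.40% in 390-5d-390c (2.27 to 2.54), 2.82% in 390c-5d-390c (2.66 to 2.99), 2.92% in 390c-3d-390c (2.55 to 3.33), 2.24% in 390c-3d (1.96 to 2.54) and 2.79% in 390-3d (2.61 to 2.97), below the even share. Counted with 1 nt either side or by distinct sequences, it stood above the even share in all 5 libraries, at 1.24 to 2.06 and 1.21 to 1.49 times that share.

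The first comparison asked what a near-complete miR390 match at the 5′ site did to the 5d reporter that kept its 3′ site. Insert siRNAs were lower in 390c-5d-390c than in 390-5d-390c, at a ratio of 0.674 (0.658 to 0.690), and so were all reads between the sites (0.679, 0.671 to 0.687). Upstream reads were higher, at 1.14 (1.12 to 1.17). At the 5′ site itself the strands turned, with 86.9% sense reads in 390-5d-390c and 30.0% in 390c-5d-390c. Native-site reads include those of endogenous TAS3a, which in the 390c lines, where the reporter lacks them, were sense for 89.3% of 346, 90% of 70 and 78.8% of 80 reads. Those are few beside the 6137 reads at the 5′ site in 390-5d-390c and the 2781 in 390-3d. Depth differs, and the endogenous share within the native-site lines cannot be counted. miR390 was lower, at 371 against 499 RPM (0.743, 0.721 to 0.766). Reporter siRNAs under the fixed rule had the opposite direction to the insert, at 906 against 831 RPM (1.09, 1.07 to 1.11).

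siRNAs of loci without miR390 sites stood close together in this pair. TAS1a, TAS1b, TAS1c, TAS2 and TAS4, which depend on miR173 or miR828, together gave 7476 against 7386 RPM (1.01, 1.0 to 1.02). Their ratios ranged from 0.974 for TAS2 to 1.28 for TAS4. TAS3a reads as a whole had a ratio of 0.695 (0.687 to 0.702), while those absent from both reporters of the pair had 1.03 (0.980 to 1.08). TAS3b (AT5G49615) had 1.07 (0.977 to 1.18), but 93.4 to 98.8% of its reads in the 5 libraries also matched TAS3a, so its ratios are not specific to the locus. Its 72 and 19 reads with a single genome position had 2.75 (1.64 to 4.82), and TAS3c (AT5G57735) 3.87 (1.11 to 20.7) on 16 and 3 reads. The 10 PPR phasiRNA genes, whose transcripts are diced after cleavage by tasiRNAs or microRNAs, together had 1.02 (0.994 to 1.05).

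Of 90 microRNAs compared in this pair, 6 passed the rule upwards and 1 downwards, and the 5th to 95th percentiles of log2 ratios were -0.66 to 1.08. The age and leaf list split, with miR319, a regulator of TCP genes in leaf growth, at 4.32 times (4.05 to 4.62) and miR156, the juvenile-phase microRNA, at 0.484 times (0.477 to 0.492), and 7 of its 9 families inside the rule. Highest were miR8175 (log2 3.36), miR319a (2.29), miR393a-3p (1.41), miR393a-5p (1.32), which targets auxin receptors, and miR394a (1.13). Lowest was miR156a-5p (-1.05). Per microRNA read the median log2 ratio moved from -0.06 to 0.15, 8 passed upwards and 0 downwards, and miR156 stood at 0.559 times. By RPM no family of the auxin, copper, phosphate, sulfate, TAS trigger or AGO and DCL feedback lists passed. miR395 of the sulfate list, at 1.79 times (1.23 to 2.66) on 99 and 40 reads, passed at 2.07 per microRNA read and at 2.03 per genome-matched 21-nt read. Of 1192 genes, 121 passed upwards and 16 downwards, around a median log2 ratio of 0.44. Per microRNA read 260 and 6 passed, and by reads with a single genome position 6 and 2 of 207. They were led upwards by MEE38 (AT3G43160, 3.44 times), AT3G33537 (3.22), AT2G01023 (3.07), AT5G29465 (3.00) and AT5G00590 (2.96). Downwards they were STP1 (AT1G11260), a hexose transporter, at 0.376 times, then NUDX1 (0.385), AT5G39530 (0.385), AT3G01710 (0.409) and MPS1 (0.423), which overlap tRNA genes. By reads with a single position MEE38 had 1.68 (0.910 to 3.23), AT3G33537 4.17 (1.42 to 16.6), AT5G29465 5.80 (0.778 to 257), AT5G00590 2.96 and STP1 0.380, and AT2G01023 had 1 and 0 such reads.

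The second comparison asked what removal of the 3′ site did to the 3d reporter with the 390c site. Loss of the site did not end siRNA production: insert siRNAs stood at 183 RPM in 390c-3d and 118 RPM in 390c-3d-390c (1.55, 1.44 to 1.67). Per mature microRNA read the ratio was 0.953 and per genome-matched 21-nt read 1.13, so its direction rested on the scaling. Reporter siRNAs had 1.29 (1.24 to 1.35), which turned to 0.795 and 0.941 under those scalings. Reads between the sites had 1.06 (1.03 to 1.09) and upstream reads 1.14 (1.11 to 1.17), and both also turned, to 0.654 and 0.700 per microRNA read. Sequence from the 3′ site on gave 0.594 times the reads (0.449 to 0.787), but native 3′ site reads of endogenous TAS3a count only in 390c-3d-390c. Over sequence that both reporters hold, the ratio was 1.89 (0.852 to 4.59) on 25 and 9 reads, so a difference there was not detectable at this depth.

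Most endogenous loci lay near even in this pair by RPM. TAS3a reads as a whole had 1.04 (1.02 to 1.06). TAS3a reads absent from both reporters had 0.932 (0.850 to 1.02), TAS3b 0.928 (0.787 to 1.10; 2.04, 0.509 to 11.7, by 9 and 3 single-position reads) and TAS3c 0.679 (0.156 to 2.95). The other TAS loci had 1.12 (1.11 to 1.13), with TAS2 at 1.40 and TAS4 at 0.735, and PPR phasiRNAs 1.08 (1.03 to 1.13). miR390 had 1.04 (0.985 to 1.09). Per microRNA read the other TAS loci turned to 0.688 and PPR phasiRNAs to 0.661, while TAS3a reads absent from both reporters moved to 0.573, TAS3b to 0.571 and miR390 to 0.636. Of 66 microRNAs, 3 passed upwards and 0 downwards, with 5th to 95th percentiles of -0.52 to 0.97: miR319a (log2 1.92), miR158a-3p (1.36) and miR775 (1.18). Per microRNA read the median log2 ratio moved from 0.10 to -0.60, and 1 passed upwards and 8 downwards. Within the lists miR319 alone passed by RPM, at 2.62 times (2.02 to 3.42), and stood at 1.61 times per microRNA read. miR393 of the auxin list, at 0.671 times (0.595 to 0.756) by RPM, passed downwards at 0.412 per microRNA read and at 0.488 per genome-matched 21-nt read. Of 314 genes, 3 passed upwards and 8 downwards, per microRNA read 2 and 50, and by single-position reads 0 and 1 of 74. PSEUDOSRKA (AT4G21370), a pseudogene of the self-incompatibility receptor kinase locus, gave 180 reads in 390c-3d and 0 in 390c-3d-390c, none of them with a single position. PSEUDOSRKA was 40.8-fold higher against the floor of 3 counts, and at least 32.8-fold higher by its 95% interval. AT4G21366 overlaps it, and AT3G42240 followed at 2.37 times (4.76, 1.09 to 43.1, by 14 and 2 single-position reads). AT1G28715, AT1G09045, AT1G28765, AT1G45229 and AT1G28710, at 0.344 to 0.353 times, overlap tRNA genes.

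The third comparison asked what the 5′ site's form did when it was the reporter's only miR390 site. With the native site in 390-3d, insert siRNAs were at 1.73 times their level with the 390c site in 390c-3d (1.65 to 1.82), and reads between the sites at 1.83 times (1.79 to 1.87). The exact unit of the insert went the other way, at 0.602 (0.426 to 0.846) on 63 and 82 reads. Upstream reads were lower, at 324 against 949 RPM (0.342, 0.331 to 0.353). So did transgene reads outside the reporter's TAS3a part, at 0.310 (0.293 to 0.329) for 21 nt and 0.311 (0.295 to 0.328) for 24 nt, so the lower level was not particular to the region next to the site. Reads at the 5′ site were sense for 82.9% in 390-3d and 27.4% in 390c-3d. Reporter siRNAs under the fixed rule were lower in 390-3d, at 0.596 (0.572 to 0.620). CHLI1 (AT4G18480), the magnesium chelatase subunit gene also known as SULFUR, gave 16.5 RPM in 390-3d against 5.81 in 390c-3d (2.84, 2.18 to 3.74).

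The insert difference had about the size seen at loci that do not need miR390. Other TAS loci were higher in 390-3d by 1.61 times (1.60 to 1.63), from 1.24 for TAS1b to 1.76 for TAS4, and PPR phasiRNAs by 1.63 (1.58 to 1.69). TAS3a reads absent from both reporters were higher by 2.66 times (2.48 to 2.86), TAS3b by 2.74 (2.43 to 3.10), again mostly on reads shared with TAS3a, and TAS3c by 2.19 (0.747 to 7.78), the last within counting error. The 16 and 9 single-position reads of TAS3b had 1.39 (0.580 to 3.58). TAS3a reads as a whole, which include reads that the reporters also hold, had a smaller ratio of 1.36 (1.34 to 1.38). AFB2 and AFB3, auxin receptor genes, gave 1.79 (1.30 to 2.5) and 1.89 (1.41 to 2.55) times the siRNAs, and TIR1 and AGO1 intervals spanned 1. miR390 differed little, at 363 against 313 RPM (1.16, 1.11 to 1.21).

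The median microRNA sequence was higher in 390-3d, with a log2 ratio of 0.61 over 81 compared. The rule was passed by 18 upwards and 4 downwards, with 5th to 95th percentiles of -0.66 to 2.30. Mature microRNA reads together were near even, at 13.6% of reads in 390-3d and 13.4% in 390c-3d. miR166, the most abundant family of the lists, was lower, at 0.746 times (0.744 to 0.749). In the auxin list 2 of 4 families passed, miR160, a repressor of ARF genes, at 8.08 times (4.57 to 15.6) and miR393 at 2.5 (2.27 to 2.75). In the age and leaf list 2 of 9 passed, miR319 at 3.57 and miR159, which targets GAMYB genes, at 3.60 times. The copper list had miR397 at 2.31 times, and of the phosphate list miR827 stood at 0.470 times. Named by the rule were miR160a-5p (log2 3.27), miR394a (3.26), miR843 (2.74), miR396a-3p (2.37) and miR3932b-5p (2.30), and downwards miR847 (-1.41), miR396b-5p (-1.17), miR827 (-1.09) and miR156d-3p (-1.03). Of 612 genes, 40 passed upwards and 3 downwards around a median of 0.51, and by single-position reads 9 and 0 of 124. Highest were AT2G14420 (3.57 times), AT3G43828 (3.18), AT1G37735 (3.03), HAM2 (2.96) and HAM1 (2.94). By single-position reads AT3G43828 had 3.08 (2.45 to 3.91), AT1G37735 3.92 (0.438 to 185) on 5 and 1 reads, HAM2 1.96 and HAM1 1.90, and AT2G14420 had 0 and 2 such reads. HAM1 and HAM2 are GRAS genes of the shoot meristem with a full match to miR171a-3p, which itself was 553 of the 589 and of the 585 reads counted there in 390-3d. PSEUDOSRKA was at 0.00435 times (0.00011 to 0.0246) on 1 read against 180, with AT4G21366 that overlaps it, and AT2G07777 at 0.350 times.

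The fourth comparison set the 3d against the 5d insert in reporters with the 390c site and the native 3′ site. Insert siRNAs were lower in 390c-3d-390c than in 390c-5d-390c, at 118 against 580.3 RPM (0.203, 0.190 to 0.216), and stayed lower per microRNA read (0.398) and per genome-matched 21-nt read (0.315). SiRNAs over the insert's edges differ between these reporters, and insert siRNAs that both can make had 0.241 (0.221 to 0.263), or 0.472 per microRNA read. The exact unit went the other way, at 1.82 (1.04 to 3.14) on 24 and 36 reads, and ATTTCCGTGACACTTAAAGGG stood at 25.3 against 24 RPM. Reporter siRNAs were at 349 against 906 RPM (0.385, 0.370 to 0.400) and reads between the sites at 0.461 times (0.450 to 0.471), which moved to 0.755 and 0.903 per microRNA read. Upstream reads were at 0.747 times (0.728 to 0.767), which turned to 1.47. The strands at the 5′ site were alike, with 27.4 and 30.0% sense reads.

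Most endogenous siRNAs were lower too in 390c-3d-390c by RPM, but by less. TAS3a reads as a whole had 0.613 (0.602 to 0.625). The other TAS loci had 0.646 (0.639 to 0.653), from 0.530 for TAS2 to 1.26 for TAS4, TAS3a reads absent from both reporters 0.536 (0.496 to 0.578), TAS3b 0.634 (0.550 to 0.728; 0.114, 0.0230 to 0.347, by 3 and 72 single-position reads), PPR phasiRNAs 0.680 (0.654 to 0.708) and miR390 0.816 (0.780 to 0.853). Per microRNA read the other TAS loci turned to 1.27, TAS3b to 1.24, PPR phasiRNAs to 1.33, miR390 to 1.60 and TAS3a reads absent from both reporters to 1.05. TAS3c had 0.855 (0.245 to 2.44), and CHLI1 1.24 (0.854 to 1.79).

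Of 83 microRNAs compared in this pair, 0 passed upwards and 15 downwards, with 5th to 95th percentiles of -3.11 to 0.43. Per microRNA read the median log2 ratio moved from -0.41 to 0.56, and 17 passed upwards and 7 downwards. miR319a was lowest (log2 -5.96), then miR8175 (0.0276 times, 0.000693 to 0.158, on 1 read against 99). Next were miR393a-5p (0 reads against 210, 25.6-fold lower against the floor, with a ratio of up to 0.0485), miR394a (-3.70) and miR160a-5p (-3.21). Of the lists, miR319 stood at 0.0319 times, miR165, which targets HD-ZIP III genes, at 0.447, miR172 at 0.416, miR827 at 0.448 and miR160 at 0.195, which moved to 0.0626, 0.876, 0.817, 0.878 and 0.383 per microRNA read. miR156 and miR157, at 1.5 and 1.17 times by RPM, passed upwards at 2.94 and 2.29 per microRNA read and stood at 2.32 and 1.81 per genome-matched 21-nt read. Of 947 genes, 487 passed downwards and 11 upwards around a median of -1.03. Per microRNA read the median moved to -0.05, with 86 downwards and 83 upwards, and by single-position reads 25 of 148 passed downwards and 0 upwards. Lowest were AT3G43566 (0.109 times), AT4G07491 (0.130), AT1G42695 (0.146), AT2G07798 (0.148) and AT1G42050 (0.154), 4 of them pseudogenes and each with 0 or 1 single-position reads in 390c-3d-390c. AT5G39530 and NUDX1 (4.11 times), AT3G01710 (3.86), AT1G28715 (3.49) and AT1G28710 (3.48) were highest, all of which overlap tRNA genes, and tRNA reads made up 10.6% of 390c-3d-390c against 4.99% of 390c-5d-390c.

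**Figure D3:**
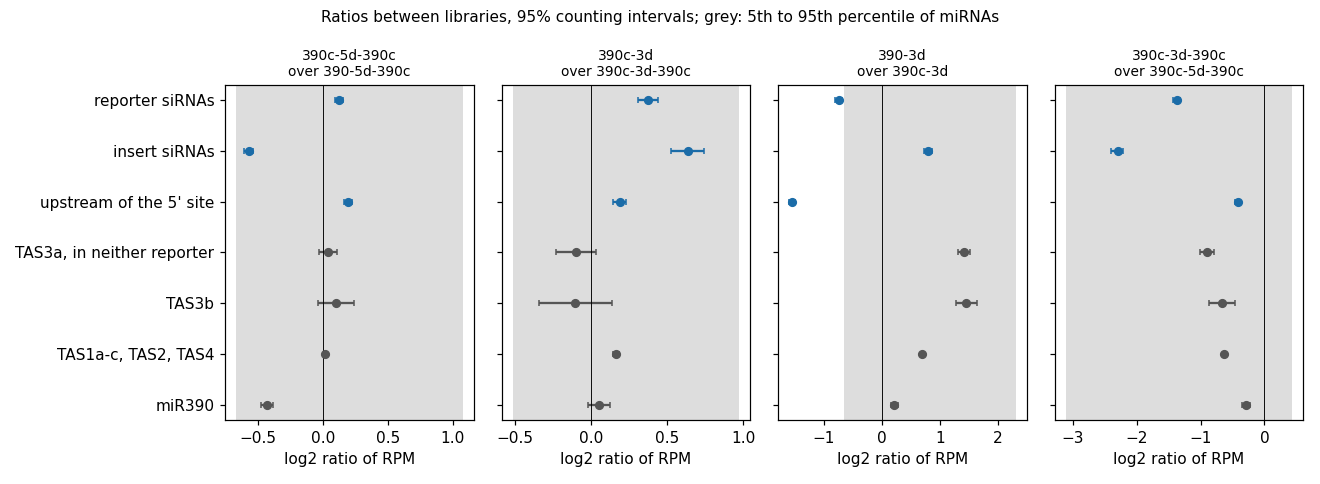
Log2 ratios of RPM (x axis) of reporter regions, TAS loci and miR390 in the 4 comparisons, as points with 95% counting intervals over a grey band from the 5th to the 95th percentile of microRNAs. The insert ratio is 0.674, 1.55, 1.73 and 0.203 from left to right and lies inside the band each time. Per mature microRNA read the insert ratio of the pair that differs in the 3′ site turns to 0.953.

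The libraries also differed in make-up. The 21-nt class made up 23.9% of reads in 390-5d-390c (23.8 to 23.9), 21.1% in 390c-5d-390c, 14.5% in 390c-3d-390c (14.4 to 14.5), 19.3% in 390c-3d and 18.7% in 390-3d. The 24-nt class made up 15.1, 21.1, 18.2, 18.3 and 19.8%. Intervals not shown equal the share at this rounding or differ by its last digit. rRNA gave 17.5 to 22.4% of reads, and tRNA 7.26, 4.99, 10.6, 6.73 and 8.47%. Mature microRNAs were lowest in 390c-3d-390c, at 8.23% against 13.4 to 18.6% in the other libraries.

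**Figure D4:**
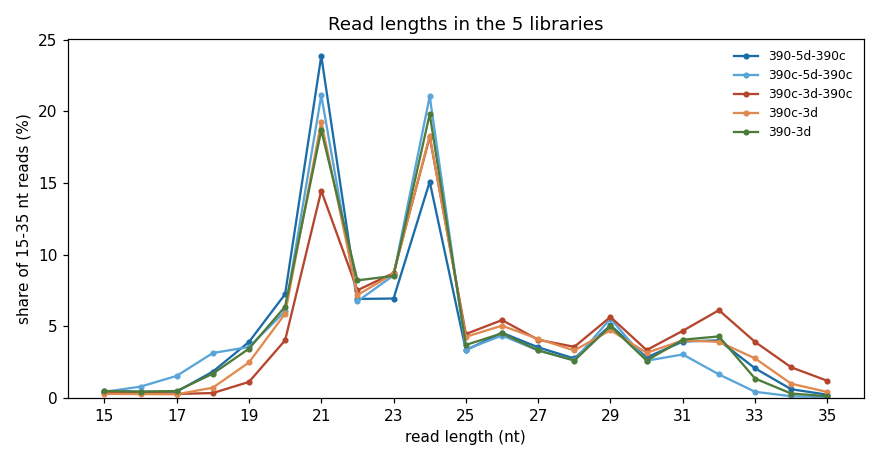
Share of reads (y axis, %) at each length from 15 to 35 nt (x axis) in the 5 libraries, 1 line per library. Peaks stand at 21 and 24 nt, and the 21-nt share runs from 14.5% in 390c-3d-390c to 23.9% in 390-5d-390c.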

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

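Of the tests in this part, those of the reporter RNA amount, the endogenous reads, the single factor for the library, base composition and sequencing error were chosen after their results were seen. No group had the 4 samples needed to look for a sample far from the others.

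In 390-3d against 390c-3d, insert siRNAs were higher (1.73, but 0.602 for the exact unit) while siRNAs from upstream of the 5′ site were lower (0.342). Endogenous TAS3a reads counted upstream are argued against, since transgene reads outside TAS3a had a ratio of 0.310 (0.293 to 0.329) and TAS3a reads absent from both reporters were higher (2.66). The insert rise by itself was near that of the other TAS loci (1.61), so a general rise of phased siRNAs in 390-3d stays open for that part but does not cover the upstream fall. A different amount of reporter RNA alone, which would move the reporter's siRNAs by 1 factor, is argued against, since reads over the replaced 3′ site had a ratio of 1.51 (1.19 to 1.92), 4.42 times (3.37 to 5.81) that of the upstream reads. The form of the 5′ site and differences between lines or plants remain open, untested with 1 library per line.

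Insert siRNAs were lower in 390c-3d-390c than in 390c-5d-390c (0.203, and 0.241 over those that both reporters can make), although the exact unit was not (1.82). One factor for the whole library is argued against, since the ratio of the shared insert siRNAs divided by that of the other TAS loci was 0.373 (0.338 to 0.411). GC content alone is argued against by 10000 random sets of TAS1 and TAS2 siRNAs in the GC classes of 14 shared insert siRNAs. These 14 had at least 20 reads each and a ratio of 0.232, against a median of 0.760 over the sets. The 14 overlap within 1 insert and are not independent, so the 0% of sets as low (lowest 0.338) does not measure chance. Other features of their sequence were not tested. The place of the insert may underlie the difference, as a hypothesis that 1 library per line leaves untested, and differences between lines or plants remain open as well.

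Antisense reads of the 3 libraries with the 390c site that end 2 nt beyond the cut carried a last base that the reporter lacks in 71.7% of reads in 390c-5d-390c, 60.6% in 390c-3d-390c and 63.9% in 390c-3d, against 1.03 and 0% (up to 2.27%) with the native site. Ends at neither miR390 cut had such shares as well, native-site libraries included, with 93.0 to 100% at position 830 of TAS3a and 68.8 to 98.0% at 614 over the 5 libraries. In 390-5d-390c the ends at 616 and 617 of the native site had 43.3% of 275 reads and 19.3% of 820. The last base was T in 96 of the 119 such reads at 616 and in 155 of 158 at 617. Sequencing error is argued against, since the lowest share, 60.6% (54.7 to 66.2), compares with medians of 0.741 to 2.03% over the other ends, and antisense reads of the same 3 libraries that held the position inside differed there in at most 0.422% (0.0871 to 1.23). A wrong base in the built 390c site is argued against, since reads of either strand that held the position at least 2 nt from their ends carried another base there in 0.139, 0.113 and 0.183% of reads, the last with an interval of 0.0377 to 0.533. A base added where a cut template ends stays open, since at the 3′ site's cut 16% of 25 reads in the 5d libraries (4.54 to 36.1) and 0 of 7 in 390c-3d-390c carried such a base, too few to decide, and it would not cover the ends away from the cuts.

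Reads flagged for the transgene by the authors also fell outside the reporter's TAS3a part, in vector sequence outside the main measures, of which only the third comparison gives ratios. The 21-nt ones gave 413 RPM in 390-5d-390c, 366 in 390c-5d-390c, 349.5 in 390c-3d-390c, 319.9 in 390c-3d and 99.3 in 390-3d, above the 0.356 RPM that a count of 0 allows at most. The 24-nt ones gave 300.1, 443, 571, 393 and 122 RPM. Further 21-nt reads with no exact match lay near an rRNA with up to 2 substitutions, at 1325, 597, 5039.6, 4188 and 1309.7 RPM.

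The ratio of 390c over 390 at the 5′ site lay on either side of 1 in the 5d and the 3d reporters for 2 endogenous measures, although barely above 1 in the 5d pair for the other TAS loci, with 1.01 (1.0 to 1.02) and 0.620. TAS3a reads absent from a library's own reporter had 1.14 and 0.415, but these are unequal sets, since native 5′ site reads count only in the 390c lines. Over TAS3a reads absent from both reporters of a pair the ratios were 1.03 (0.980 to 1.08) and 0.376, which leaves no opposite direction for TAS3a. The difference between the pairs was not tested.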

How the results depend on the processing

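The insert alone, insert siRNAs that both reporters of a pair can make, the exact insert unit, all reporter-only sequences, gene counts under other settings, any match to the reporter and TAS3a reads absent from the library's own reporter or from both reporters of a pair were alternatives chosen after seeing the data. Of the results under all alternatives, 31 stayed within the counting interval of the main value or within 1.5 times a count. Another 75 left it without being scored as a change of direction, and 27 were scored as one. The 75 include shares and total counts, which were not scored for direction. They also include miR390 for the 3′ site, at 1.04 by RPM with an interval that spans 1 and 0.636 per microRNA read. Changes of direction may therefore exceed 27. Depth limits 390c-3d-390c most, where a count of 0 allows 0.356 RPM. No paired analysis was possible because each line had 1 library. Values below follow the comparisons as 5′ site in 5d lines, 3′ site, 5′ site in 3d lines and insert, or the libraries as 390-5d-390c, 390c-5d-390c, 390c-3d-390c, 390c-3d and 390-3d. For each change below the cause was not tested, unless stated.

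Per microRNA read, reporter siRNAs went to 1.26, 0.795 (reversed) and 0.755 for the 5d, 3′ site and insert comparisons. In the same order miR390 went to 0.858, 0.636 and 1.60 (reversed), TAS3a to 0.802, 0.638 (reversed) and 1.20 (reversed), and the other TAS loci to 1.17, 0.688 (reversed) and 1.27 (reversed), with 1.59 for the 5′ site in 3d lines. The cause is the scaling itself, as the microRNA share of reads differed between libraries. Per genome-matched 21-nt read, reporter siRNAs went to 1.23, 0.941 (reversed) and 0.597.

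With 20-24 nt reads, reporter siRNAs had 1.22 for the 5d lines, 0.488 for the 3d lines and 0.421 for the insert, and TAS3a 0.730 for the 5d lines and 1.01 for the 3′ site. By the insert alone, the reporter ratio was 0.674 (reversed), 1.55, 1.73 (reversed) and 0.203, and by those that both reporters can make the last was 0.241. By the exact unit it was 0.428 (reversed), 2.32, 0.602 and 1.82 (reversed). By all reporter-only sequences it was 1.36 for the 3′ site. By reads absent from both reporters of a pair, the TAS3a ratio was 1.03 and 0.932 (each on the other side of 1, with an interval that spans 1), 2.66 and 0.536. By reads absent from the library's own reporter, which are unequal sets, it was 1.14, 0.972, 2.41 and 0.497.

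The 21-nt share by distinct sequences was 8.26, 7.63, 6.76, 7.15 and 7.70%, and of 18-28 nt reads 29.9, 25.2, 20.1, 24.3 and 23.1%, where the smaller denominator is the cause.

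The most used register of reporter siRNAs, as a fold over an even spread, was 4.00, 3.66, 3.03, 2.90 and 5.10 with 1 nt either side, and 4.85, 5.25, 3.94, 3.94 and 7 by distinct sequences. By the insert alone it was 5.62 in 390-5d-390c, 6.63 in 390c-3d-390c, 6.07 in 390c-3d and 6.99 in 390-3d, and by any match to the reporter 8.13, 8.78, 7.23, 6.41 and 8.04. The fixed rule kept only abundant sequences, so the folds of reporter siRNAs, by distinct sequences included, have no even spread as a baseline. The 3′ site register of TAS3a reversed from under to over an even spread with 1 nt either side, at 1.88, 1.83, 2.06, 1.24 and 1.39, and by distinct sequences, at 1.31, 1.24, 1.43, 1.21 and 1.49. By reads absent from the reporter it was 0.181, 0.199, 0.406, 0.679 and 0.644.

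MicroRNAs with a fold of 2 or more numbered 16, 16, 50 and 32 at a minimum of 10 reads and 2, 1, 8 and 4 at 1000 reads, where the number compared changed. Per microRNA read they numbered 9 for the 3′ site (1 higher, 8 lower) and 24 for the insert (17 higher, 7 lower). Genes with a fold of 2 or more numbered 266, 52, 40 and 169 per microRNA read, and 8, 1, 9 and 25 by reads with a single genome position, where the number compared fell.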

Other observations

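The hypotheses of this section are given with the patterns above, and the values here were chosen after they were seen. Sense reads that began within the 5′ site differed in their most used start with each form of the site, although native-site reads include those of endogenous TAS3a. With the native site they began mostly at position 618 of TAS3a, 2 nt upstream of the cut position, for 50.1% of 9065 reads in 390-5d-390c and 53.8% of 3702 in 390-3d, and for 0.276 and 0.243% at the cut position itself. With the 390c site they began most often at the cut, for 49.0% of 1758 reads in 390c-5d-390c, 48.8% of 365 in 390c-3d-390c and 45.9% of 667 in 390c-3d, and for 6.66, 3.29 and 5.70% at 618. Position 617 was a common start with either form. It held 23.5, 24.4 and 26.2% in these 390c libraries, and 28.7 and 26.4% in 390-5d-390c and 390-3d.

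PSEUDOSRKA, a pseudogene of the self-incompatibility receptor kinase locus, gave 21-nt siRNAs almost only in 390c-3d, with 180 reads (14.5 RPM, 12.5 to 16.8). The other libraries had 7 reads in 390-5d-390c, 5 in 390c-5d-390c, 0 in 390c-3d-390c (up to 0.356 RPM) and 1 in 390-3d. Its level in 390c-3d was 34.7 times that of 390-5d-390c and 66.9 times that of 390c-5d-390c, and none of its reads in 390c-3d had a single position in the genome. miR173, the trigger of TAS1 and TAS2, gave 7.06, 6.94, 5.22, 6.37 and 7.14 RPM in the order 390-5d-390c, 390c-5d-390c, 390c-3d-390c, 390c-3d and 390-3d. miR828, the trigger of TAS4, gave 1 read in 390c-5d-390c and 0 in the other libraries. miR163 gave 128, 160.4, 153, 146 and 224 RPM in the same order, and miR846 17.2, 19, 15, 22.7 and 22 RPM.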
